A study of Homo sapiens with 21 samples.

How the data were processed

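RNA was sequenced from GTL-16, a human gastric carcinoma cell line that carries an amplified MET gene, and from 6 subclones of it, named A to F, that grow in the presence of crizotinib, an inhibitor of the MET kinase. There were 7 groups of 3 samples, 21 libraries in all. Per the labels' protocols, the resistant subclones were kept in 1 uM crizotinib and were then cultured without the drug for 7 to 10 days before RNA was collected, and stranded libraries were made from messenger RNA, pooled and sequenced as read pairs. The labels do not say that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

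The authors deposited one table of log2 values for 57665 genes in the 21 libraries. Undoing the log gave values that summed to between 999976 and 999981 in each library, so the deposited log2 values were taken as log2 TPM, a share of transcripts corrected for gene length. The lowest value, -5.18 on the log2 scale or 0.0276 TPM, was shared by many genes and was treated as a floor, set to 0 TPM here. How that floor was chosen is not given in the sources used here. The submitters' processing notes name the build GRCh38 and the tools FastQC 0.11.5, Salmon 0.9.1 and sleuth 0.29.0, with no role for any of them. TPM keep no record of the number of reads, so the depth of each library is unknown and no counting interval can be given. The number of genes above the floor, 23881 to 26089 per library, is the nearest measure of depth available. Because TPM values share a fixed total, a change in a few abundant genes shifts all others, and the mitochondrially encoded genes alone took 24.7% to 29.0% of each library.

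Of the 57665 gene identifiers, 57068 (99.0%) were found in GENCODE release 29, 92.5% with the same version number, and coordinates and gene types were taken from that release on GRCh38. A symbol was found for 56591 genes. The table was made at the level of whole genes, so reads that fit several similar genes could have been divided between them. Values of genes with close paralogs are uncertain, and the main ones are marked.

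Genes above 1 TPM in at least 3 libraries were tested, 16466 in all, of which 12516 were protein coding. Values were transformed to log2(TPM + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust moderation, in one model of the 7 groups with no other covariate. Tables were handled with the R package data.table (version 1.17.8) and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Log2 fold changes are on the log2(TPM + 1) scale and understate the change of low genes. A gene was called changed when its Benjamini-Hochberg adjusted p was under 0.05 and its absolute log2 fold change was at least 1, that is at least 2-fold. The comparisons were each of the 6 clones against parental, the mean of the 6 clones against parental, the 15 pairs of clones, and an F-test for any difference among the 6 clones, called with a range of clone means of at least 1. Adjusted p-values are from limma with Benjamini-Hochberg adjustment throughout. The design had been written for either counts or a normalized unit, and the part for a normalized unit was used.

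The genes named were chosen by a rule fixed before the data were examined. MET is given in every group. For each clone against parental, the rule took the 8 largest rises and the 8 largest falls among called protein-coding genes with a symbol, a mean of at least 10 TPM in the higher group, and every clone library on the same side of every parental library, leaving out Y-linked genes and XIST. From each gene list described for a clone it took up to 4 measured members with the smallest adjusted p, and any called member. It also took up to 10 genes called in one direction in all 6 clones, ranked by their smallest absolute log2 fold change, the 10 genes with the largest range of clone means among those past the F-test, and the 5 largest rises and 5 largest falls in the mean of the clones, under the same rule of type and level. Genes outside the rule are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

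Gene lists of pathways, lineage markers and markers of other cell types, 39 in all, were also fixed before the data were examined. Lists with at least 5 tested members, 35 in all, were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 210 tests of 35 lists in 6 clones, and again with a correlation estimated from the residuals. For each list the text gives how many measured members were called up or down over all genes tested. The count adjusted over the list alone was the same for every list and clone except 1 test of drug metabolism genes in clone B, with 2 members higher adjusted over the list alone and 1 over all genes.

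The procedure was tested on simulated data in which 200 of the 16466 genes of a clone A against parental comparison were given known changes. The changes were set on the transformed log2 scale, so 4-fold and 2.3-fold refer to that scale and not to TPM. Of 50 genes lowered 4-fold 48 were called, and of 50 raised 4-fold 49 were called. At a 2.3-fold change 46 of 50 lowered and 43 of 50 raised genes were called. Of 16266 unchanged genes 3 were called. Recovery was not split by expression level, so these counts do not show how well changes of low genes are found. Other splits of the samples, leaving out each library in turn, pseudocounts of 0.1 and 5, rescaling between libraries by a trimmed mean or the upper quartile, no filter, a filter of 5 TPM, thresholds without a fold and at 4-fold, limma without trend and robust moderation, the replicate number as a block, and fits of the compared libraries alone were planned. The values as deposited with no pseudocount, nuclear protein-coding genes rescaled to one total, and the count shared by all clones without clone D were added after seeing the data. Tests that need read counts were not run.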

Results

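Gene expression was measured by RNA sequencing in GTL-16 cells, a gastric carcinoma line with an amplified MET gene, and in 6 crizotinib-resistant subclones of it, named A to F. Each of the 7 groups had 3 libraries. The comparisons ask how clones selected in a single high-dose step differ from parental cells and from each other. No subclone grown without selection was sequenced, so changes tied to resistance cannot be told apart from those that any subclone would carry. The depth of the 21 libraries is unknown, because the deposited values are TPM, and 23881 to 26089 genes lay above the floor in each. The correlation of log2(TPM + 1) across genes, which are not independent replicates, was at least 0.978 between libraries of one group and at most 0.979 between libraries of different groups. Levels are given as mean ± SD in TPM with n = 3, and log2 fold changes ± SE on the log2(TPM + 1) scale.

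MET, the receptor tyrosine kinase that crizotinib inhibits (ENSG00000105976.14, chromosome 7, 116672390 to 116798386 in GRCh38), stood at 859 ± 2.30 TPM in parental cells and stayed among the abundant transcripts in every clone. Clone D had 337 ± 14.8 TPM, a log2 fold change of -1.35 ± 0.04 (limma BH-adjusted p = 3.23e-14), and was the only clone in which MET passed the 2-fold threshold. Clones A, B, C and F had 614 ± 37.9, 621 ± 17.0, 654 ± 16.5 and 601 ± 15.2 TPM, with log2 fold changes of -0.48, -0.47, -0.39 and -0.52. Clone E had 1073 ± 39.7 TPM, a log2 fold change of 0.32 ± 0.04. MET was lower in clone D than in each of the other 5 clones, with limma BH-adjusted p-values of 5.43e-11 or less and log2 differences from -0.83 to -1.67.

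Several genes that flank MET on chromosome 7 fell with it in clone D. Of 8 measured members of a list of 7q31 neighbours, 4 fell and 1 rose, with a median log2 fold change of -1.003 (camera BH-adjusted p = 3.27e-04, and 0.0140 with an estimated correlation). On adjusted p alone 6 were lower and 1 higher. CAPZA2, an actin capping subunit (chromosome 7, 116811070 to 116922049), went from 1254 ± 23.7 to 560 ± 6.38 TPM. ST7 (chromosome 7, 116953238 to 117230103) went from 192 ± 5.57 to 71.2 ± 2.72 TPM, and TES (chromosome 7, 116210493 to 116258783) from 690 ± 4.45 to 303 ± 7.14 TPM. MDFIC, farther away at chromosome 7, 114922154 to 115019202, went from 114 ± 2.77 to 45.8 ± 0.990 TPM. CAV1, the caveolin gene at chromosome 7, 116524785 to 116561184, rose instead from 49.4 ± 2.00 to 230 ± 13.1 TPM. CAV2 beside it had a log2 fold change of -0.32 ± 0.05. The list was also lower, with no member past 2-fold, in clone A (camera BH-adjusted p = 2.29e-05, estimated 0.0118), clone B (5.37e-04, estimated 0.0177) and clone F (0.00417, estimated 0.0430). It was not called in clone C (camera BH-adjusted p = 0.180) or clone E (0.558).

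**Figure D1:**
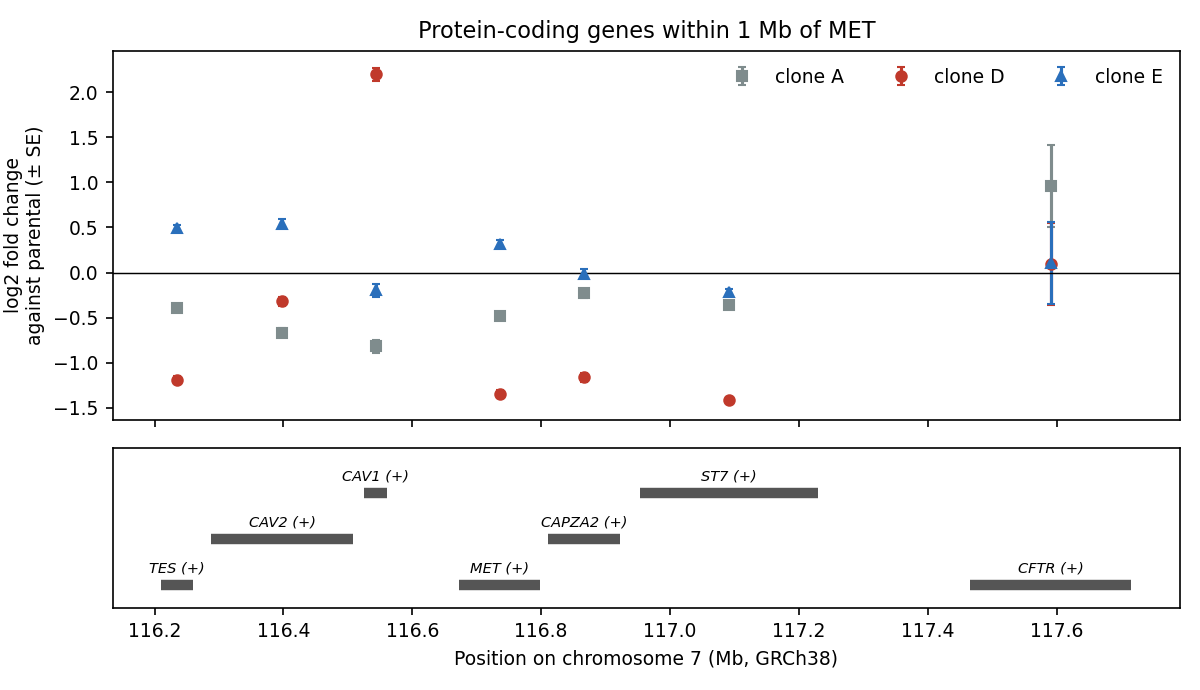
Log2 fold change against parental (± SE, log2(TPM + 1) scale, n = 3 per group) of the tested protein-coding genes within 1 Mb of MET in clones A, D and E, above a map of the genes on chromosome 7 in GRCh38. In clone D, TES, MET, CAPZA2 and ST7 lay between -1.42 and -1.16, and CAV1 lay at 2.20.

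FGF3, HBEGF and IGF2, genes of secreted growth factors, set some clones apart from others. FGF3, a fibroblast growth factor (ENSG00000186895.2, chromosome 11, 69809969 to 69819024), was at 0.0201 ± 0.0348 TPM in parental cells. It reached 55.3 ± 0.458 TPM in clone A, 59.5 ± 5.96 in clone B, 41.4 ± 2.38 in clone F and 7.00 ± 0.977 in clone C, and was at 0.0389 ± 0.0338 TPM in clone D and 0.0179 ± 0.0309 in clone E. Each of clones A, B, C and F differed from D and from E in FGF3 (limma BH-adjusted p of 1.91e-14 or less). HBEGF, an EGF receptor ligand (ENSG00000113070.7, chromosome 5, 140332843 to 140346631), rose in clone E from 8.03 ± 0.489 to 100 ± 3.00 TPM, a log2 fold change of 3.49 ± 0.07 (limma BH-adjusted p = 5.72e-16). Each other clone lay below clone E in HBEGF, with log2 differences from -4.62 to -4.12 (limma BH-adjusted p of 6.25e-17 or less). IGF2, insulin-like growth factor 2 (ENSG00000167244.18, chromosome 11, 2129112 to 2149603), rose in clone D from 4.74 ± 0.331 to 111 ± 2.60 TPM, a log2 fold change of 4.28 ± 0.10 (limma BH-adjusted p = 6.57e-16). IGF2 was also called in clone A at 15.6 ± 2.15 TPM, clone C at 12.8 ± 1.87 and clone F at 11.8 ± 0.939, and the calls in C and F were lost with a pseudocount of 5. KITLG, the KIT ligand, fell in clone D from 8.82 ± 0.711 to 0.137 ± 0.0593 TPM. A list of growth factor ligands, which does not hold FGF3, had 18 measured members. It was called in clone B alone, as lower, with 1 member past 2-fold (camera BH-adjusted p = 1.07e-04, and 0.0136 with an estimated correlation). That member was AREG, at 41.6 ± 0.416 TPM in parental cells and 13.8 ± 1.78 TPM in clone B. Members of the list past 2-fold were 1 higher and 4 lower in clone A and 1 higher and 3 lower in clone C. They were 2 and 2 in clone D, 2 and 1 in clone E and 1 and 1 in clone F.

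**Figure D2:**
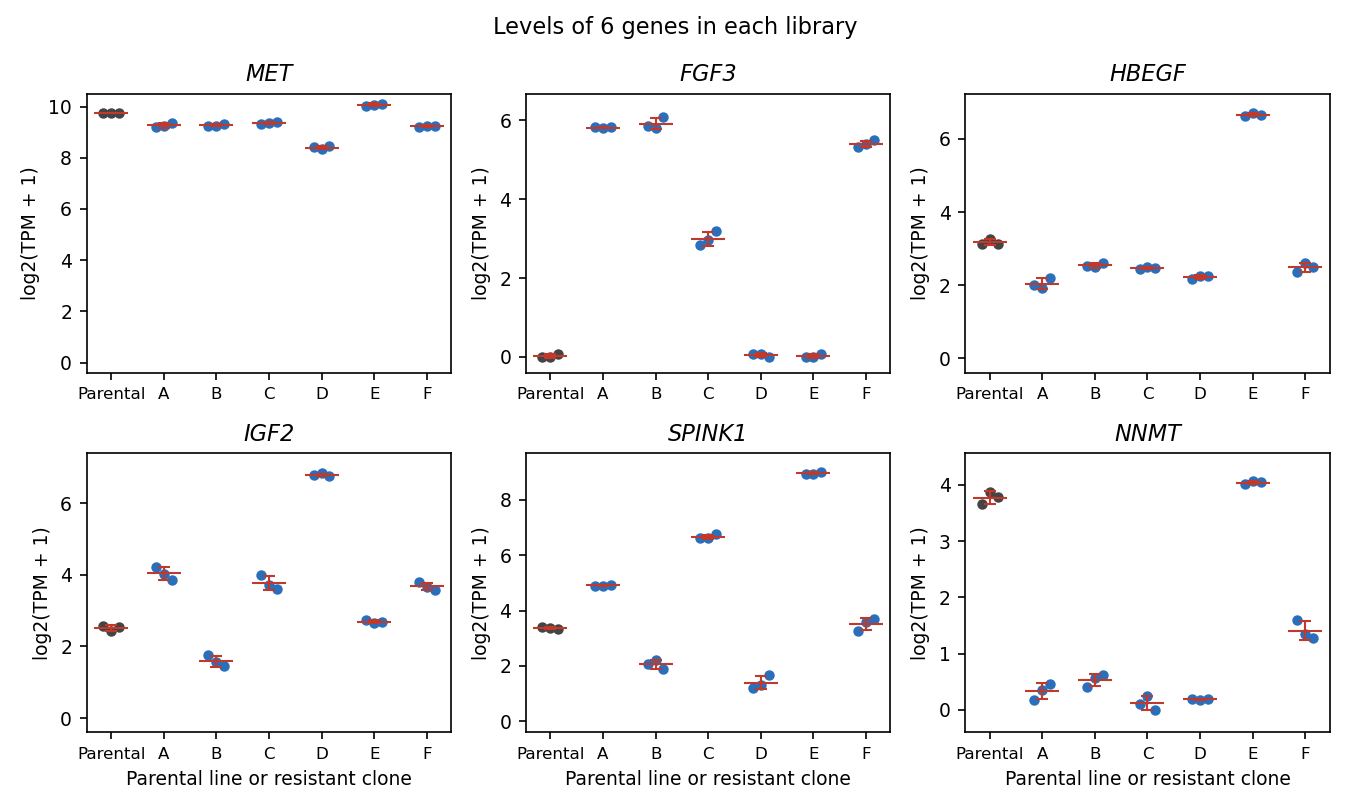
Level of 6 genes, as log2(TPM + 1), in each of the 21 libraries (dots), with the group mean (red line) and SD (bar), for the parental line and clones A to F. FGF3 was high in clones A, B, C and F, HBEGF was highest in clone E at 100 TPM, and IGF2 was highest in clone D at 111 TPM.

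The number of changed genes differed between clones. Against parental cells, 319 of 16466 tested genes were changed in clone A (165 higher, 154 lower), 127 in clone B (36 higher, 91 lower) and 225 in clone C (78 higher, 147 lower). In clone D 885 were changed (594 higher, 291 lower), in clone E 337 (173 higher, 164 lower) and in clone F 290 (157 higher, 133 lower). Without the 2-fold requirement, 2612 genes in clone B to 7892 in clone D had a limma BH-adjusted p under 0.05. The share of called genes that were higher depended on scaling in clone C, at 34.7%, 45.2% after trimmed-mean rescaling and 45.5% after upper-quartile scaling. In clone E it was 51.3%, 62.6% and 60.0%. In clone D it was 67.1%, 69.0% and 68.8%. That share in clone D was 58.5% with at least 5 TPM in 3 libraries and 53.2% with a pseudocount of 5.

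**Figure D3:**
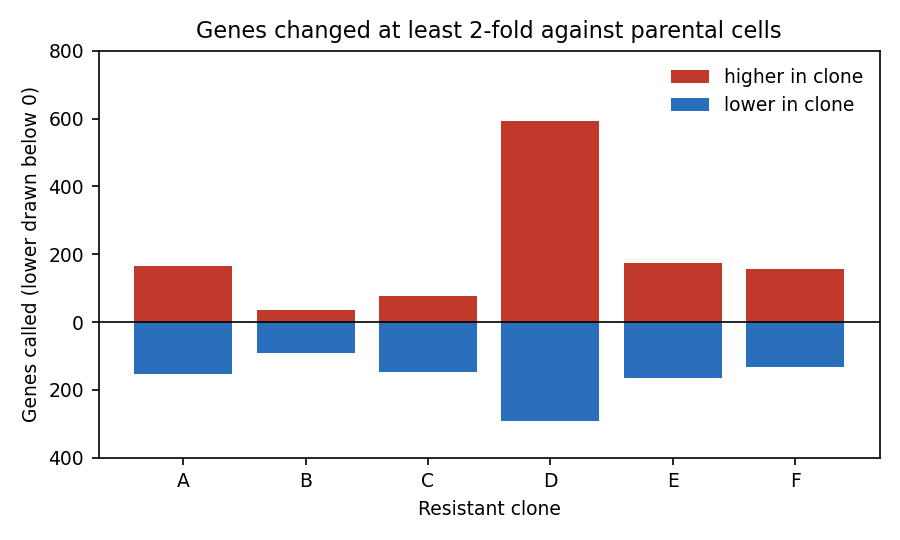
Number of genes called at least 2-fold higher (above 0) or lower (drawn below 0) than parental in each resistant clone, with 3 libraries per group. Clone D had 594 higher and 291 lower genes, and clone B had 36 and 91.

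No gene was called higher in all 6 clones, and 6 genes were called lower in all 6. COL12A1, a fibril-associated collagen, went from 7.33 ± 0.893 TPM in parental cells to between 0.201 TPM (clone F) and 2.53 TPM (clone E). CXCL3, a chemokine with close paralogs whose values are uncertain, as are those of CXCL1, went from 13.7 ± 1.38 TPM to between 3.16 TPM (clone A) and 6.04 TPM (clone B). CELF2, an RNA-binding protein, went from 5.68 ± 0.708 TPM to between 0.295 TPM (clone E) and 1.92 TPM (clone B). The other 3, chosen after their values were seen, were an antisense gene without a symbol (ENSG00000235978), a Y_RNA gene and RNU6-494P. The comparisons share the 3 parental libraries, which cannot be split, so part of this agreement can come from shared controls. With a pseudocount of 5, the calls of CELF2 in clones A, B, C, D and F, of CXCL3 in B, D, E and F and of COL12A1 in B and E were lost. Of all called genes, 933 were called in 1 clone, and 67 were higher in some clones and lower in others.

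In the mean of the 6 clones, 63 genes were higher and 78 lower than parental by at least 2-fold. The mean treats these clones as fixed, so its SEs hold the spread between libraries within groups and leave out that between clones. Among protein-coding genes with a mean of at least 10 TPM in parental cells or over the clones, and every clone library on one side of every parental library, the largest rises of the mean included the collectrin gene CLTRN (2.15 ± 0.07), the gastric trefoil peptide TFF1 (1.44 ± 0.06), CCN2 (1.32 ± 0.05) and SYTL5 (1.27 ± 0.04). Within those limits the largest falls were in the succinate receptor SUCNR1 (-2.11 ± 0.07), the chemokine CXCL1 (-1.60 ± 0.08), the collagen hydroxylase PLOD2 (-1.47 ± 0.08), CXCL3 (-1.43 ± 0.07) and the oncostatin M receptor OSMR (-1.29 ± 0.06). Outside them, FGF3 (3.34 ± 0.06) and NNMT (-2.67 ± 0.08) moved more in the mean, though not in every clone, and COL12A1 (-2.24 ± 0.12) and CELF2 (-1.67 ± 0.09), below 10 TPM, fell more than SUCNR1 and CXCL1 respectively.

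In clone A, besides FGF3, the largest rises included epithelial differentiation and surface genes. DHRS9, a retinol dehydrogenase, went from 0.747 ± 0.124 to 38.7 ± 2.70 TPM, and CRABP2, a retinoic acid binding protein, from 5.43 ± 0.362 to 30.2 ± 3.40 TPM. CLTRN went from 1.35 ± 0.105 to 12.5 ± 0.467 TPM. SPRR3 and SPRR1B, precursors of the cornified envelope, went from 0.253 ± 0.209 and 1.62 ± 0.572 to 17.4 ± 1.31 and 26.1 ± 4.09 TPM. Of 16 measured intestinal markers 6 rose and 1 fell (camera BH-adjusted p = 4.19e-06, and 0.0128 with an estimated correlation), among them CEACAM6, from 48.0 ± 2.03 to 307 ± 11.4 TPM, and KRT20, from 0.334 ± 0.181 to 6.97 ± 0.750 TPM. DNAJC12 fell from 49.3 ± 1.76 to 2.92 ± 0.410 TPM. NNMT, nicotinamide N-methyltransferase (ENSG00000166741.7, chromosome 11, 114257787 to 114313285), fell from 12.7 ± 1.05 to 0.264 ± 0.124 TPM, SERPINA1 from 22.4 ± 1.31 to 1.39 ± 0.236 TPM and SUCNR1 from 14.99 ± 0.901 to 1.00 ± 0.228 TPM. The genes of clone A named here had limma BH-adjusted p-values of 2.21e-09 or less. SPRR and CEACAM genes have close paralogs, so their values are uncertain.

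Clone B had the fewest changed genes, and inflammatory and ERK pathway genes were lower in it. Besides FGF3, FXYD2, a sodium pump regulator, rose from 29.7 ± 3.32 to 70.5 ± 2.72 TPM. CEACAM5, an adhesion protein with close paralogs, fell from 159 ± 5.31 to 23.6 ± 0.856 TPM, the deacetylase HDAC9 from 12.7 ± 0.331 to 2.37 ± 0.127 TPM and the chemokine CXCL8 from 15.5 ± 0.872 to 3.85 ± 0.173 TPM. These 4 genes had limma BH-adjusted p-values of 2.25e-07 or less. Of 18 measured NF-kB and inflammatory genes 4 fell and 0 rose (camera BH-adjusted p = 6.38e-06, and 0.0128 with an estimated correlation). That list was higher in clone F (camera BH-adjusted p = 0.0206), a call lost with an estimated correlation (0.155). Of 26 measured ERK pathway targets 2 fell past 2-fold and 18 were lower on adjusted p alone (camera BH-adjusted p = 2.21e-11, and 0.0189 with an estimated correlation). Integrin and matrix adhesion genes, with 1 of 24 past 2-fold, and heat shock and immediate early genes, with 2 of 22, were also lower as lists (camera BH-adjusted p = 2.33e-06 and 1.12e-08, and 0.0128 for each with an estimated correlation). The ERK target list was also lower in clones A (camera BH-adjusted p = 0.00635), E (0.00102) and F (0.0198), calls that were lost with an estimated correlation (0.318, 0.235 and 0.410). Heat shock and immediate early genes were lower in clone E as well (camera BH-adjusted p = 1.08e-05, estimated 0.0419), and their call in clone A (0.0276, estimated 0.277) and that of integrin and matrix adhesion genes in clone C (0.00988, estimated 0.109) were lost.

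In clone C the largest rises included genes of the digestive tract. SPINK1, a secreted trypsin inhibitor (ENSG00000164266.10, chromosome 5, 147824568 to 147831786), went from 9.38 ± 0.198 to 101 ± 5.50 TPM, and LIPF, gastric lipase, from 0.437 ± 0.212 to 10.0 ± 0.708 TPM. TFF1 went from 26.7 ± 1.02 to 105 ± 7.02 TPM and REG4 from 76.7 ± 6.44 to 219 ± 17.2 TPM. Of 16 measured intestinal markers 4 rose and 0 fell (camera BH-adjusted p = 3.13e-06, and 0.0128 with an estimated correlation). NNMT fell to 0.0876 ± 0.0937 TPM, SPTSSB, a subunit of serine palmitoyltransferase, from 112 ± 12.7 to 23.2 ± 0.927 TPM and UBE2L6, an interferon-induced conjugating enzyme, from 28.7 ± 2.25 to 6.70 ± 0.983 TPM. These 7 genes had limma BH-adjusted p-values of 2.76e-10 or less. DUSP6, a feedback phosphatase of ERK, fell from 78.4 ± 2.88 to 36.1 ± 1.38 TPM. The ERK target list, with 3 of 26 members lower, had a camera BH-adjusted p of 0.00223 that became 0.261 with an estimated correlation.

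Clone D had the most changed genes. CST1 and CST4, secreted cystatins, rose from 30.04 ± 2.78 and 0.234 ± 0.111 to 317 ± 5.30 and 25.8 ± 2.65 TPM, with values that are uncertain because of close paralogs. CLTRN rose from 1.35 ± 0.105 to 45.1 ± 5.65 TPM, IL1RL1, the interleukin 33 receptor, from 0.172 ± 0.0568 to 20.7 ± 0.848 TPM and TIMP3, a metalloproteinase inhibitor, from 0.215 ± 0.0550 to 17.1 ± 0.0132 TPM. CYP24A1, which inactivates vitamin D, was listed at 0 in parental cells and at 13.7 ± 1.298 TPM in clone D. SPTSSB fell to 3.33 ± 0.886 TPM, NPNT, an integrin ligand, from 32.4 ± 0.485 to 0.820 ± 0.210 TPM, AGR3 from 365 ± 5.84 to 23.5 ± 2.30 TPM and PTGS2, the inducible cyclooxygenase, from 8.97 ± 0.386 to 0.0636 ± 0.0584 TPM. These genes had limma BH-adjusted p-values of 5.00e-13 or less. Of 22 measured TGF-beta targets 6 rose and 0 fell, among them CCN2, from 2.50 ± 0.134 to 37.1 ± 1.41 TPM. For the TGF-beta targets list in clone D, a camera BH-adjusted p of 0.00215 became 0.168 with an estimated correlation and 0.0609 when genes had to reach 5 TPM. Of 20 measured YAP/TAZ targets 2 rose and 0 fell (camera BH-adjusted p = 0.00280, and 0.0631 with an estimated correlation).

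In clone E the largest rise past the rule for naming genes was in SPINK1, from 9.38 ± 0.198 to 497 ± 12.6 TPM, a log2 fold change of 5.59 ± 0.11 (limma BH-adjusted p = 2.70e-16). FABP1, a fatty acid binding protein of intestine and liver, went from 5.90 ± 0.461 to 118 ± 7.57 TPM, and BHLHE41 from 0.816 ± 0.161 to 19.5 ± 1.15 TPM. Of 16 measured intestinal markers 7 rose and 0 fell (camera BH-adjusted p = 1.50e-06, and 0.0128 with an estimated correlation). GNAI1, a G protein subunit, fell from 13.9 ± 1.02 to 0.873 ± 0.374 TPM, the claudin CLDN2 from 84.3 ± 0.460 to 16.4 ± 0.898 TPM, IGFBP2 from 131 ± 3.35 to 32.8 ± 0.226 TPM and EGR1 from 25.5 ± 0.410 to 5.29 ± 0.723 TPM. These genes had limma BH-adjusted p-values of 3.74e-09 or less. Of 34 measured cell cycle genes 29 were lower on adjusted p alone, with a median log2 fold change of -0.36 (camera BH-adjusted p = 6.43e-10, and 1.44e-04 with an estimated correlation). That list was also lower in clone F, with 14 lower on adjusted p alone and 0 past 2-fold (camera BH-adjusted p = 0.0159, and 0.0430 with an estimated correlation). The list was lower in clone E than in each of the other 5 clones (camera BH-adjusted p of 0.00966 or less with an estimated correlation). Its 1 member past 2-fold in clone E, MCM3, went from 269 ± 3.92 to 134 ± 1.36 TPM, a log2 fold change of -1.005. The call of MCM3 in clone E was lost after trimmed-mean rescaling (-0.92) or upper-quartile scaling (-0.93), on nuclear protein-coding genes alone (-0.93), with a pseudocount of 5 (-0.98), and without parental replicate 2 or clone E replicate 3 (-0.997 each). Mitochondrially encoded genes took 28.7% ± 0.400 of the clone E libraries and 25.2% ± 0.376 of the parental libraries.

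Interferon response genes moved in opposite directions in different clones. Of 27 measured members 14 rose and 0 fell in clone E, with a median log2 fold change of 1.02 (camera BH-adjusted p = 3.03e-20, and 1.44e-04 with an estimated correlation). In clone E, ISG15 went from 40.3 ± 3.78 to 93.7 ± 9.39 TPM, IFI6 from 4.68 ± 1.51 to 19.6 ± 1.35 TPM and IFIT1 from 2.14 ± 0.168 to 10.8 ± 0.314 TPM. The list was lower, with no member rising past 2-fold, in clone B (7 fell, camera BH-adjusted p = 2.00e-20, estimated 1.44e-04), clone C (6 fell, 1.23e-07, estimated 0.0118), clone D (7 fell, 1.83e-05, estimated 0.0183) and clone F (6 fell, 1.22e-06, estimated 0.0128). IRF9, a subunit of the interferon-activated transcription factor, went from 18.7 ± 1.05 to 5.05 ± 0.886 TPM in clone B, and BST2, tetherin, from 12.5 ± 1.32 to 1.71 ± 0.268 TPM in clone D. In clone A 1 member rose and 1 fell (camera BH-adjusted p = 0.692). The list was higher in clone E than in each other clone (camera BH-adjusted p of 4.38e-04 or less with an estimated correlation). Antigen presentation genes were higher in clone E, with 2 of 17 past 2-fold (camera BH-adjusted p = 4.86e-07, estimated 0.00476), and PSMB9, an immunoproteasome subunit, went from 3.12 ± 0.748 to 17.0 ± 1.49 TPM there. They were lower in clone B, with 0 past 2-fold (camera BH-adjusted p = 6.16e-09, estimated 0.00156), and in clone C, with 2 (5.45e-04, estimated 0.0198), where PSMB8 went from 9.91 ± 0.0577 to 0.895 ± 0.0307 TPM. Their call in clone F, as lower (camera BH-adjusted p = 0.0230), was lost with an estimated correlation (0.108). Most called interferon genes were low, and with a pseudocount of 5 no member stayed past 2-fold in clones C and F. Some calls near 2-fold were lost when a single library was left out. They included OAS2, IFI27 and RSAD2 in clone E, IFI44 in clone B, OAS2 in clone C and IFIT3 in clone F.

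Cholesterol synthesis genes were lower as a list in each of the 6 clones. The 6 comparisons share the parental libraries, so they are not independent and part of this agreement can come from shared controls. Of 24 measured members 8 fell past 2-fold in clone E and 0 in the other clones, while 11 in clone B to 22 in clone E were lower on adjusted p alone. HMGCS1, the enzyme ahead of HMG-CoA reductase, stood at 78.0 ± 3.82 TPM in parental cells and 27.2 ± 0.964 TPM in clone E, and the sterol sensor INSIG1 at 123 ± 1.90 and 48.0 ± 1.19 TPM. The median log2 fold changes were -0.52, -0.16, -0.36, -0.49, -0.76 and -0.36 in clones A to F, with camera BH-adjusted p-values of 4.63e-16, 0.00128, 8.10e-08, 3.63e-09, 8.81e-15 and 1.86e-11. With an estimated correlation the camera BH-adjusted p was 0.0128 in clone A, 0.0453 in D, 0.0136 in E and 0.0250 in F, and the calls in B (0.261) and C (0.0696) were lost.

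**Figure D4:**
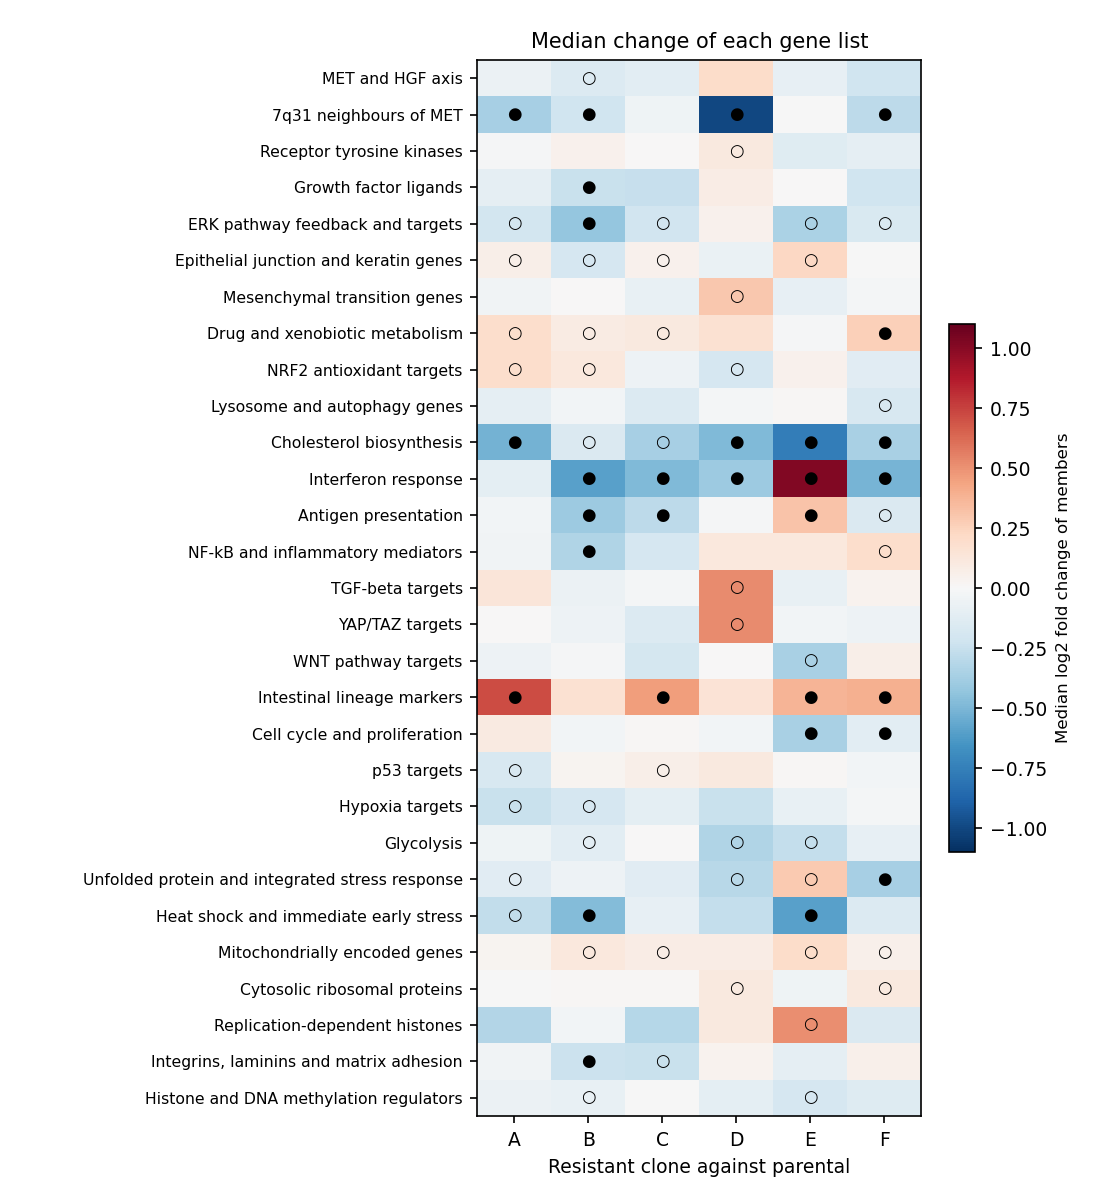
Median log2 fold change against parental (colour, log2(TPM + 1) scale) of 29 gene lists, each called in at least 1 of the 6 clones. Circles mark a camera BH-adjusted p under 0.05 at the preset correlation, filled where the call held with an estimated correlation, and interferon response genes had a median of 1.02 in clone E and -0.60 in clone B.

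In clone F, KRT15, a keratin of basal epithelium, went from 5.72 ± 1.19 to 26.7 ± 0.808 TPM, C15orf48 from 3.94 ± 0.837 to 22.3 ± 1.33 TPM and the drug-metabolizing enzyme CYP3A5, uncertain because of close paralogs, from 4.09 ± 0.207 to 17.3 ± 1.66 TPM. Drug metabolism genes were higher as a list, with 3 higher and 2 lower of 23 (camera BH-adjusted p = 0.00128, and 0.0453 with an estimated correlation). The calls of that list in clones A (0.00988), B (0.0155) and C (0.00988) were lost with an estimated correlation (0.1003, 0.118 and 0.1003 by camera, BH-adjusted). DNAJC12 fell to 4.26 ± 0.234 TPM, SLC38A4, an amino acid transporter, from 37.3 ± 1.58 to 6.94 ± 0.311 TPM and ETV1, a transcription factor downstream of ERK, from 39.5 ± 1.92 to 9.87 ± 0.591 TPM. These 6 genes had limma BH-adjusted p-values of 2.16e-06 or less. Genes of the unfolded protein and integrated stress response were lower as a list, with 4 down and 2 up of 28 (camera BH-adjusted p = 2.29e-05, and 0.0419 with an estimated correlation), and TRIB3 went from 87.8 ± 4.43 to 24.3 ± 0.783 TPM. That list was also lower in clone A (camera BH-adjusted p = 0.0129, estimated 0.212) and clone D (0.00988, estimated 0.193) and higher in clone E (3.95e-04, estimated 0.0789), 3 calls that were lost with an estimated correlation. Intestinal markers, with 3 of 16 higher, were called as well (camera BH-adjusted p = 1.08e-05, and 0.0140 with an estimated correlation).

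Across the 6 clones, the F-test with a 2-fold range called 2214 genes, 1678 of them protein coding, and 12026 genes passed without the fold requirement. Pairs of clones differed in 146 genes (A and C) to 1237 genes (D and E). Clones A, C and F lay nearest to each other by this count, with 191 genes between C and F and 202 between A and F. The largest range of clone means was that of SPINK1, at 497 TPM in clone E and 1.65 TPM in clone D.

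Lists of drug efflux transporters and of RAS and MAPK cascade components had few 2-fold changes. Of 27 measured components of the RAS and MAPK cascade 0 passed in any clone, with camera BH-adjusted p-values from 0.0530 in clone B to 0.950 in clone E. The RAS-RAF-MAPK pathway components list in clone B had a median log2 fold change of -0.18 and passed as lower without parental replicate 1 (camera BH-adjusted p = 0.0357), without the filter on low genes (5.32e-04), with the replicate block (0.0450) and on the compared libraries alone (0.0294). Of 11 measured ABC drug transporters 1, ABCA3, passed in 1 clone, from 1.05 ± 0.186 to 3.36 ± 0.621 TPM in clone D. That ABCA3 call was lost with a pseudocount of 5 and without clone D replicate 2, where the log2 fold change was 0.97. Of 26 measured receptor tyrosine kinases 4 rose in clone D, EPHB6 going from 0.934 ± 0.339 to 7.49 ± 1.06 TPM. In clone E 1 fell and 0 rose, with 11 lower and 1 higher on adjusted p alone, and the list was not called (camera BH-adjusted p = 0.0946). The Receptor tyrosine kinases list in clone D had a camera BH-adjusted p of 0.0276, which became 0.325 with an estimated correlation, 0.0558 without clone D replicate 2 and 0.0545 with the 5 TPM filter. MUC20, a mucin that binds MET, rose from 15.5 ± 0.277 TPM to 56.7 ± 4.41 in clone A, 58.2 ± 0.335 in clone D and 51.8 ± 4.48 in clone F. A list of MET and HGF axis genes, with 13 measured members, was called in clone B alone, as lower (camera BH-adjusted p = 0.00704). That call was lost with an estimated correlation (0.235). Past 2-fold, 1 member rose in each of clones A, D and F, and 1 fell in each of B, C and D. Of 12 fibroblast markers 2 were measured and 0 called, of 10 endothelial markers 2 were measured and 0 called, and of 16 blood cell markers 3 were measured. Of these, CD68 rose from 3.00 ± 1.04 TPM to 10.9 ± 2.01 TPM in clone A and 14.7 ± 1.44 TPM in clone F, and the call in A was lost with a pseudocount of 5.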

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

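Some genes in this part had the largest ranges of clone means among genes past an F-test of the 6 clones. Others were named genes called higher than parental in some clones and lower in others, and MET was included as well. The F-test p-values given below come from the same data that picked these genes, so they add no separate support. The tests of gene copies and of composition for MET, and the tests of mixing into clones A, C and F, were chosen after the result was seen, and the other tests here were written before.

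Growth factor genes and MET were among the genes that differed. On the log2(TPM + 1) scale the range between the highest and lowest clone was 5.89 for FGF3 (highest in clone B), 4.62 for HBEGF (clone E), 5.22 for IGF2 (clone D) and 1.67 for MET (highest in clone E, lowest in D). Their F-test had limma BH-adjusted p-values of 5.01e-14 or less.

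Among digestive tract, surface and secreted proteins the range was 7.57 for SPINK1 (highest in clone E, lowest in D), 5.397 for FABP1 (clone E), 4.44 for CEACAM5 (clone E), 4.63 for CST4 and 4.47 for CST1 (both clone D). CEACAM5, CST1 and CST4 have close paralogs. Among enzymes, carriers and regulators it was 5.05 for DHRS9 (clone A), 4.87 for SPTSSB (clone E), 4.53 for PTGS2 (clone F), 3.83 for CRABP2 (clone A), 3.71 for CP (clone D), 3.595 for SH3BGRL (clone B) and 3.80 for C15orf48 (clone A). It was 3.21 for UBE2L6 (clone E), 3.12 for HDAC9 (clone D), 2.70 for HEPH (clone A), 2.60 for FXYD2 (clone B) and 2.29 for SLC40A1 (clone B), where the clone named has the highest mean. Their F-test had limma BH-adjusted p-values of 2.06e-12 or less.

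FGF3 rose from near 0 in clones A, B, C and F. Gain of a block of chromosome 11 would raise its neighbours too, and the medians over 12 other genes within 1 Mb were 0.23, -0.00181, 0.34 and 0.16 in A, B, C and F, far below the FGF3 log2 fold changes of 5.79, 5.89, 2.96 and 5.38. A smaller gain in clone C stays open, since chromosome 11 had a median of 0.28 there. The largest excess of any other FGF gene in these clones was 1.89 TPM, which gives no sign of reads shared with a related gene. Reads of a related gene assigned wholly to FGF3 would leave no such excess, so that explanation stays open. Mixing of clone A into clone B would carry other genes along, and the median share of the clone A rise found in B over 68 other genes was -0.0230, against 1.08 for FGF3. For mixing of 1 other clone into clone A only B held enough FGF3, at a share of at least 0.826, and 23 of 7055 protein-coding genes at 10 TPM or more in B stayed below 0.5 times the level in A that this share needs. SH3BGRL, for example, was at 11.9 ± 1.09 TPM in B and 1.63 ± 0.285 in A. For clone F such genes numbered 6 with A as the source and 5 with B, where a single library had at most 3 below 0.5 times the others of its group. The median share of the rise alone would allow mixing of B into A (0.637, against 0.930 for FGF3), of A into F (0.451, against 0.748) and of B into F (0.497, against 0.696), but the genes that stay too low argue against mixing into A and F. Mixing into clone C cannot be told apart from a change in C itself, since the shares needed were only 0.0930 to 0.141 and 0 genes lay that low with B or F as the source. A change of FGF3 itself in clones A, B and F is a hypothesis, found and tested on the same data, and gain of FGF3 without its neighbours was not tested.

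MET and several of its neighbours fell together in clone D. The median over 5 genes above 20 TPM within 1 Mb of MET was -1.16, which may come from fewer copies of the amplified region, although CAV1 rose. Composition of the TPM scale would shift all genes, whose median was 0.0327. With any 1 library left out, the MET log2 fold change closest to 0 was -1.31, so no single library made it. DNA copies were not measured, and lower transcription across the region stays open.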

How the results depend on the processing

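The counts of changed genes moved with the threshold and with the treatment of low values, and much less with scaling. Trimmed-mean rescaling, upper-quartile scaling, limma without trend and robust moderation, the replicate block, the compared libraries alone and nuclear protein-coding genes alone kept each count within 1.5 times its value, where run. No result reversed. The values as deposited, nuclear protein-coding genes alone and the count without clone D were chosen after seeing the data. Pairs of clones are given in the order AB, AC, AD, AE, AF, BC, BD, BE, BF, CD, CE, CF, DE, DF and EF where all moved, and the cause of the changes was not tested except where the setting itself alters the threshold or the genes tested.

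On adjusted p alone, the counts against parental in clones A to F were 4248, 2612, 4678, 7892, 6461 and 5280, and the pairs of clones had 3966, 2895, 6737, 7107, 4711, 3984, 6863, 6334, 4736, 7669, 6950, 4640, 8811, 6276 and 7542. In that setting, 301 were called in one direction in all 6 clones, 5043 genes changed in the mean of the clones and 12026 differed among the 6 clones. At 4-fold or more, the counts against parental in clones A to F were 47, 18, 33, 145, 35 and 35, and the pairs of clones had 63, 26, 78, 60, 20, 37, 168, 68, 51, 121, 47, 27, 204, 89 and 81. In that setting, 0 were called in one direction in all 6 clones, 11 genes changed in the mean of the clones and 365 differed among the 6 clones. With log2 TPM as deposited, the counts against parental in clones A to F were 645, 319, 582, 1585, 837 and 640, and the pairs of clones had 696, 345, 1179, 1036, 463, 584, 1383, 1000, 594, 1596, 1036, 492, 2024, 1080 and 1265. In that setting, 17 were called in one direction in all 6 clones, 405 genes changed in the mean of the clones and 3556 differed among the 6 clones. With a pseudocount of 0.1, the counts against parental in clones A to F were 607, 290, 519, 1512, 751 and 601, and the pairs of clones had 648, 316, 1126, 954, 439, 536, 1319, 922, 563, 1507, 945, 442, 1947, 1041 and 1177. In that setting, 13 were called in one direction in all 6 clones, 350 genes changed in the mean of the clones and 3437 differed among the 6 clones. With a pseudocount of 5, the counts against parental in clones A to F were 103, 30, 59, 265, 98 and 78, and the pairs of clones had 134, 42, 172, 139, 51, 67, 265, 146, 81, 243, 112, 48, 414, 177 and 190. In that setting, 0 were called in one direction in all 6 clones, 29 genes changed in the mean of the clones and 739 differed among the 6 clones.

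With at least 5 TPM in 3 libraries, the count against parental was 542 in clone D, and the pairs had 96 (AC), 366 (AD), 130 (AF), 504 (BD), 504 (CD), 125 (CF), 813 (DE) and 371 (DF). In that setting, 3 were called in one direction in all 6 clones and 1413 differed among the 6 clones. With no filter on low genes, 10 were called in one direction in all 6 clones. With an estimated correlation, 30 gene list tests were called. With clone D left out, 11 were called in one direction in all the other 5 clones.

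Leaving out each library in turn gave 314 to 341 in clone A, 125 to 137 in clone B, 220 to 239 in clone C, 878 to 930 in clone D, 323 to 349 in clone E and 273 to 302 in clone F against parental. The pairs gave 344 to 378 (AB), 142 to 156 (AC), 591 to 612 (AD), 459 to 532 (AE), 182 to 227 (AF), 225 to 245 (BC), 796 to 822 (BD), 452 to 482 (BE), 256 to 275 (BF), 816 to 843 (CD), 410 to 433 (CE), 184 to 211 (CF), 1216 to 1268 (DE), 557 to 636 (DF) and 582 to 612 (EF). The mean of the clones gave 135 to 143 genes, genes called in one direction in all 6 clones 5 to 9, the F-test 2206 to 2247 and gene list calls 73 to 78.

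Replicate numbers did not pair the libraries across groups, with correlations of residuals from -0.06 to 0.10 over 63 pairs and 10 of 21 libraries closest to one of their own number. With the replicate number as a block, the counts in clones A to F were 322, 129, 225, 889, 343 and 290, and the pairs had 354, 143, 598, 475, 200, 229, 804, 467, 268, 825, 413, 188, 1239, 607 and 596. With that block 140 genes changed in the mean, 6 were called in all 6 clones, 2207 differed among clones and 80 list tests were called.

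In all, 1061 values of a gene in a clone were followed, called or not. A pseudocount of 5 ended 182 calls among them, trimmed-mean rescaling 21 and upper-quartile scaling 19. Nuclear protein-coding genes alone ended 10 calls among 1037 values. Of 210 list tests 76 were called, and the estimated correlation ended 46 of these 76 calls. No filter on low genes ended 1 and added 14. The filter of 5 TPM ended 19 calls among 204 list tests. Depth is unknown in TPM, so the limit it sets on low genes cannot be given.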

Other observations

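The tests of copies and of composition for chromosome 3 were chosen after the result was seen, and the test of expression level was written before.

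Some gastric markers changed, while their list was not called in any clone. SOX2, a stomach transcription factor, fell from 9.68 ± 0.708 TPM in parental cells to 3.76 ± 0.2903 in clone A, 2.24 ± 0.161 in clone B, 2.67 ± 0.278 in clone C, 1.93 ± 0.0447 in clone E and 1.40 ± 0.0781 in clone F. TFF1 rose from 26.7 ± 1.02 TPM to 113 ± 10.1 in clone A, 105 ± 7.02 in clone C, 108 ± 10.2 in clone E and 81.2 ± 6.95 in clone F. In clone D, VSIG1 went from 230 ± 11.5 to 72.6 ± 5.75 TPM, ANXA10 from 141 ± 1.91 to 52.2 ± 0.920 TPM and GATA6 from 17.97 ± 0.540 to 6.02 ± 0.491 TPM, while TFF2 rose from 1.19 ± 0.0959 to 5.84 ± 0.668 TPM and LIPF from 0.437 ± 0.212 to 5.54 ± 0.736 TPM. The list of 14 measured gastric markers had camera BH-adjusted p-values from 0.0772 in clone C to 0.950 in clone E, and the Gastric lineage markers list in clone C passed without clone C replicate 2 (0.0382). NRF2 targets were higher as a list in clone A (camera BH-adjusted p = 0.00102) and clone B (0.00375) and lower in clone D (0.0268), and these calls were lost with an estimated correlation (0.108, 0.155 and 0.271). Of 7 measured histone genes 3 rose in clone E (camera BH-adjusted p = 4.50e-04, and 0.0696 with an estimated correlation).

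Genes of chromosome 3 were lower in several clones. Over 547 genes the median log2 fold change was -0.37 in clone A, -0.52 in C and -0.43 in F, and it was -0.29 in D. Among clones A, C and F the lowest share of 10 Mb windows with a median under -0.2 was 94.1%, which may come from fewer copies of the chromosome. In clone D, outside these tests, the share was also 94.1%. Expression level does not explain the shift in A, C and F, since the median closest to 0 among higher and lower genes was -0.369. Composition does not either, since the lowest median of the other chromosomes in these clones was -0.0574. DNA copies were not measured, so copy loss remains a hypothesis.

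Shifts appeared on other chromosomes as well, and none of them was tested. The median log2 fold change was 0.28 on chromosome 11 in clone C, 0.33 on chromosome 20 and -0.22 on chromosome 12 in clone D, and -0.23 on chromosome 18 in clone A. It was -0.20 on chromosome 15 and -0.23 on chromosome 2 in clone E.

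Other splits of the samples were counted for each number of genes. For each clone against parental, and for each pair of clones, the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05, and the real split was the 1 with the most genes each time. Fitted on those 6 libraries, the real split and the highest other gave 310 and 5 in clone A, 132 and 11 in clone B, 225 and 8 in clone C, 862 and 7 in clone D, 328 and 5 in clone E and 286 and 7 in clone F. Between clones they gave 348 and 8 (A and B), 140 and 10 (A and C), 565 and 9 (A and D), 463 and 11 (A and E), 192 and 9 (A and F), 231 and 10 (B and C), 784 and 1 (B and D), 459 and 4 (B and E), 265 and 7 (B and F), 797 and 8 (C and D), 400 and 5 (C and E), 188 and 6 (C and F), 1209 and 7 (D and E), 590 and 4 (D and F) and 580 and 6 (E and F).

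For the F-test among clones, 1 of 100 splits gave as many genes as the real 2211, the real one itself, with 790 the highest other. For gene list calls it was 1 of 100, with 76 against 66. For the mean of the 6 clones, 2 of 100 splits gave as many, with 33 genes in a 2-group fit, and for genes called in all 6 clones 3 of 100, with 6 genes. For the F-test and the gene list calls a chance split of the libraries can be excluded at 0.05, which shows only that libraries grouped by clone, since other splits mix libraries of different clones. For the mean and the shared count the splits say nothing on whether the parental line stands apart from the clones. The highest other splits of the mean and of the shared count, 599 and 290 genes, set all 3 clone D libraries against the rest or in the parental place, which points to the structure of the samples.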
